A study of Homo sapiens with 6 samples.

How the data were processed

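RNA sequencing of A549 lung adenocarcinoma cells was analysed from the files deposited by the authors, 1 per library, for 6 libraries in 3 groups of 2: cells given lentivirus with HOXB9 (WT), with HOXB9 carrying the T133A change (a threonine replaced by alanine), or labelled as a HOXB9 knockout (KO). Per the labels' protocols, cells were grown in RPMI medium with 10% serum, RNA was taken up in Trizol, and libraries followed a standard Illumina procedure. Each file holds a read count and an FPKM value per gene, as deposited by the authors, with Ensembl identifiers, positions, lengths and biotypes. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0 and the genome build GRCh38. The strand setting of the counting and the annotation release are not given in the sources used here, so overlapping genes and antisense pairs may share counts, and reads of similar gene copies may be split or dropped.

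The counts deposited by the authors were whole numbers with no normalization, over 58735 genes, of which 31579 had a count in at least 1 library. Totals ran from 16299059 to 18745432 counts per library. The deposited FPKM values divided each count by gene length and by a library size of 0.967 to 1.03 times the total count. They were used only for that check, and all results come from the counts. The files had 27 gene names that a spreadsheet had turned into dates. All 27 were restored from the gene identifier. A count of 0 allows a level of up to 3 counts, which is 0.161 to 0.182 CPM depending on the library. Where all libraries of a group had 0 counts, a fold change was given as a lower bound against 3 counts per library. With 1 to 3 counts, the ratio was given with an exact 95% counting interval. Such intervals and floors cover counting error only.

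Groups, tests, gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; robust fit, TMM scaling, filterByExpr defaults) in a single fit of all 6 libraries with group as the only term. This left 16340 genes, 13538 of them protein coding, with a biological coefficient of variation of 8.96%. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Comparisons were T133A with WT, KO with WT, and T133A with KO, and a positive log2 fold change means higher in the group named before the other. Standard errors were derived from the fold change and its F statistic. Levels are CPM after TMM scaling.

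For 35 gene lists fixed beforehand (HOX clusters, secreted factors, epithelial, mesenchymal, matrix, adhesion and signalling genes, proliferation, stress and metabolic pathways, inflammation, lineage and stemness genes, and markers of fibroblast, haematopoietic, endothelial and embryonic kidney line cells), the members called were counted over all genes tested and again adjusted over the list alone. Lists with at least 3 tested members, 33 in all, were tested against all other genes with camera (limma 3.58.1; preset correlation 0.01, prior count 2), two-sided, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Named genes are, for each comparison, the 10 largest rises and 10 largest falls among protein-coding genes with adjusted p under 0.05, an absolute log2 fold change of at least 1, at least 5 CPM in the higher group and both libraries of a group above both of the other. HOXB9 was added, and for each list up to 4 called members with the smallest adjusted p, or the most abundant member where none was called. Genes named outside this rule are said to be so.

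Because both comparisons with WT share the same libraries, their overlap was set beside 100 simulations of unchanged groups and beside the overlap of independent lists. Alternatives were RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum mean of 5 CPM, only the compared groups, the replicate number as a block, each library left out in turn (the lone library of that group is then assumed to vary like the others), a minimum log2 fold change of 1, and, for lists, an estimated correlation and fry. A correction for GC content and length (per-library loess with span 0.5 as offsets, from GENCODE 29 transcripts, with values for 99.95% of tested genes), a crossed replicate block, comparing T133A and KO each with another WT library, and leaving out mitochondrial genes were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

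The procedure was tested on simulated counts with the real means and library sizes, in which 200 genes were changed. For T133A with WT (15933 genes), edgeR recovered 32.8% of changes of 1.5-fold, 79.1% of 2-fold and 92.4% of 4-fold, and called 11 unchanged genes. For KO with WT (15927 genes) the shares were 52.2%, 59.7% and 89.4%, with 10 unchanged genes called, and for T133A with KO (15928 genes) 43.3%, 79.1% and 90.9%, with 16. Of 100 unchanged lists of 25 genes in each comparison, camera called none after adjustment with either correlation, and fry called 1 in KO with WT. The simulated genes varied independently of each other. These numbers therefore do not show that the preset correlation holds for real genes that vary together. A list of genes with planted 2-fold rises gave camera p = 0.00067, 0.000855 and 0.000659 with an estimated correlation before adjustment. Adjusted together with the unchanged lists, it did not pass (adjusted p = 0.0677, 0.0863 and 0.0665). In the real data only 33 lists were adjusted together, and genes may vary together. The planted list therefore does not show whether a real list could pass.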

Results

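RNA was sequenced from A549 cells, a line derived from a human lung adenocarcinoma and grown in RPMI medium with 10% serum. The cells had been stably transduced with lentivirus in 3 ways. The WT group carried HOXB9, a homeobox transcription factor of the HOXB cluster on chromosome 17. The T133A group carried HOXB9 with the T133A change, a threonine replaced by alanine, and the KO group was labelled as a HOXB9 knockout. Each group had 2 libraries, and there was no group with an empty vector or with untreated cells. Total counts per library were 16692104 and 17577009 in WT, 18344938 and 17027686 in T133A, and 16299059 and 18745432 in KO. Levels below are in CPM (counts scaled to a common library size), as mean ± SD of the 2 libraries of a group, and each fold change or SE rests on 2 libraries per group. A value given for a gene without a unit is its log2 fold change. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

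The libraries separated by group. The leading principal component held 68.3% of the variance and set KO (73.73 and 76.49) apart from T133A (-32.07 and -36.88) and WT (-41.53 and -39.74). The second component held 15.99% and set T133A (-34.52 and -30.11) apart from WT (31.31 and 29.75). Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 2.46 for WT, 10.1 for T133A and 12.1 for KO), and the KO and T133A pairs stood further apart than the WT pair. Genes of the mitochondrial genome took 7.87% and 7.84% of the counts in WT, 8.91% and 8.51% in T133A, and 5.60% and 4.45% in KO.

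HOXB9 itself (ENSG00000170689, chromosome 17, 48621159 to 48626356 on GRCh38, reverse strand) was counted 3807 and 3889 times in the WT libraries, 4777 and 3577 times in T133A, and 239 and 286 times in KO. Its level was 219.7 ± 4.0 CPM in WT, 242 ± 45.5 CPM in T133A and 14.95 ± 0.625 CPM in KO. The transcript was thus 14.7-fold lower in KO than in WT by edgeR's quasi-likelihood test (log2 fold change -3.88, SE 0.135, adjusted p = 3.27e-16), and higher in T133A than in KO (log2 fold change 4.02, SE 0.136, adjusted p = 1.44e-16). T133A and WT did not differ past the threshold (log2 fold change 0.14, SE 0.113, adjusted p = 0.495). That last value turned on the T133A libraries, with a log2 fold change of -0.05 without T133A replicate 1 and of 0.33 without T133A replicate 2, where it passed (adjusted p = 0.0202). The counts do not separate transcripts of the lentiviral construct from those of the cells' own gene. HOXB7 is annotated across HOXB8 and HOXB9, and HOXB3 across HOXB4, HOXB5 and HOXB6, so counts of these genes may be shared.

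**Figure D1:**
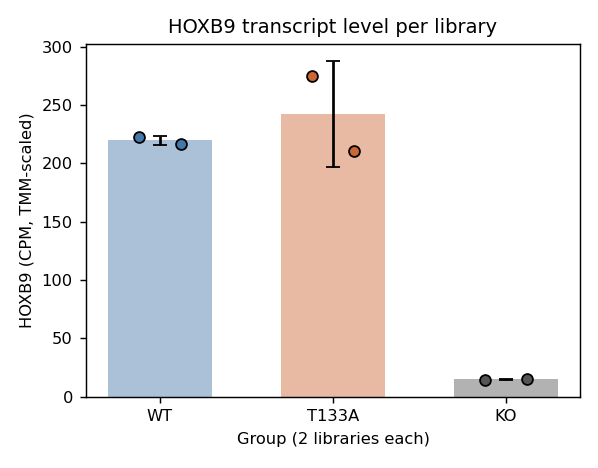
HOXB9 level in each library in CPM (vertical axis, TMM-scaled) for WT, T133A and KO. Points are libraries, bars are group means and error bars are the SD of 2 libraries; the KO mean is 14.95 CPM against 219.7 CPM in WT and 242 CPM in T133A.

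The comparison of T133A with WT asked which transcripts differ between cells given HOXB9 with and without the T133A change. The labels do not say whether the cells' own HOXB9 was intact in these groups, so the comparison may not isolate the threonine. CXCL8, which encodes interleukin-8, a chemokine that attracts neutrophils, stood at 446 ± 55.5 CPM in T133A and 12.01 ± 2.94 CPM in WT, a 37.2-fold difference (log2 fold change 5.22, SE 0.151, adjusted p = 1.51e-16; ENSG00000169429, chromosome 4, 73740506 to 73743716). PI3, encoding the elastase inhibitor elafin, rose 105-fold from 0.312 ± 0.111 to 33.7 ± 5.84 CPM (log2 fold change 6.71, SE 0.312, adjusted p = 3.36e-13; ENSG00000124102, chromosome 20, 45174876 to 45176544). KRT4, a keratin of stratified epithelia, fell from 39.6 ± 1.06 to 6.41 ± 1.67 CPM (log2 fold change -2.62, SE 0.176, adjusted p = 2.14e-10; ENSG00000170477, chromosome 12, 52806549 to 52814551), and SPDEF, a transcription factor of mucus-secreting cells, fell from 34.99 ± 1.78 to 8.39 ± 1.39 CPM (log2 fold change -2.06, SE 0.164, adjusted p = 4.86e-09).

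Among the other genes with the largest rises, the serpins SERPINB7 and SERPINB3 reached 103 ± 4.05 and 88.2 ± 3.45 CPM from 2.26 ± 0.277 and 3.92 ± 0.494 CPM in WT (log2 fold change 5.50 (SE 0.166) and 4.49 (SE 0.161)). The acute-phase gene SAA1 rose by 6.12 on the log2 scale (SE 0.403), the chemokine gene CCL20 by 5.31 (SE 0.296), and ICAM1, which encodes a leukocyte adhesion molecule, by 4.62 (SE 0.304). LRRC55, EBI3 (a subunit of interleukin-27 and interleukin-35) and C15orf48 rose by 4.95, 4.61 and 4.58. The remaining largest falls were in ENTPD2, an enzyme that breaks down extracellular ATP (-2.35), PRRT1B (-1.94), the alcohol dehydrogenase gene ADH1C (-1.91), BCAS1 (-1.89), RAP1GAP, which inactivates the GTPase RAP1 (-1.87), ANKS4B (-1.85), the prohormone convertase gene PCSK1 (-1.83) and UGT2B15, a glucuronidation enzyme (-1.77). All of these 20 genes passed edgeR's test, with adjusted p of at most 0.000143. SERPINB3 with SERPINB4, SAA1 with SAA2, and UGT2B15 with its family members have near-identical copies, so their counts are uncertain.

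**Figure D2:**
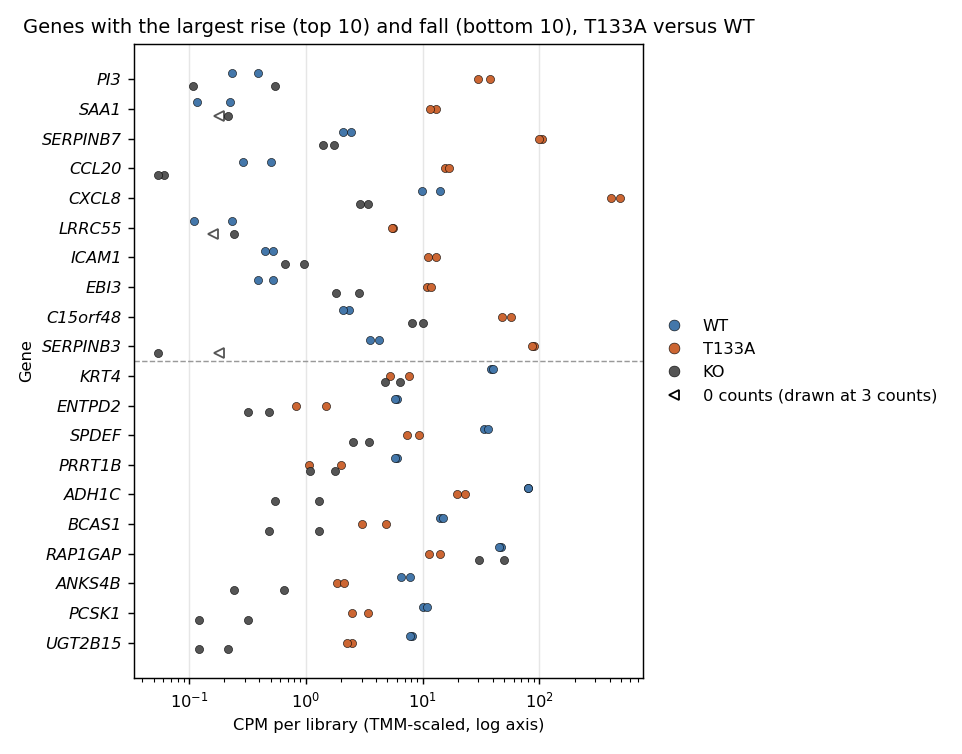
CPM in each library (horizontal log axis, TMM-scaled) of the 10 genes with the largest rise and the 10 with the largest fall in T133A against WT; points are libraries and open triangles stand for libraries with 0 counts, drawn at the level of 3 counts. CXCL8 averages 446 CPM in T133A against 12.0 CPM in WT, and KRT4 6.41 CPM against 39.6 CPM.

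edgeR called 1560 of 16340 genes tested, 912 higher and 648 lower in T133A, and 431 of them differed by at least 1 on the log2 scale (285 higher, 146 lower). The higher share was 58.5% of the calls with TMM scaling and 45.0% with scaling by library size only. The number called fell without either WT library and rose without T133A replicate 2. Each such fit left 1 library in a group, so the falls may reflect the lost replicate rather than that library. A correction for GC content and gene length, chosen after the data were seen, called 2622 genes.

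Genes of the NF-kB and inflammatory cytokine list rose together. Of 25 members tested, 24 rose and none fell (25 higher when adjusted over the list alone), with a median log2 fold change of 2.30 (camera adjusted p = 2.17e-32; adjusted p = 0.1 with an estimated correlation). The chemokine genes CXCL1 and CXCL3 rose from 49.4 ± 1.56 and 14.5 ± 0.16 CPM to 639 ± 29.6 and 137 ± 9.09 CPM (log2 fold change 3.69 (SE 0.11) and 3.24 (SE 0.125)), and CCL2, which attracts monocytes, rose from 5.73 ± 0.172 to 75.7 ± 0.484 CPM (log2 fold change 3.72, adjusted p = 2.49e-14). TNFAIP3, which encodes A20, an inhibitor of NF-kB signalling that is itself an NF-kB target, rose from 11.7 ± 0.82 to 141 ± 8.41 CPM (log2 fold change 3.58, adjusted p = 3.76e-15). The member that missed the threshold was TRAF1, named after its values were seen (log2 fold change 0.51, SE 0.224, adjusted p = 0.17). Between 22 and 25 members rose with any 1 library left out. Reads of CXCL1, CXCL2 and CXCL3 may be shared between these similar genes.

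Lists of matrix, adhesion and signalling genes also lay higher in T133A. Among integrins and matrix proteases, 8 of 23 rose and none fell (10 adjusted over the list alone; camera adjusted p = 3.24e-05, adjusted p = 0.249 with an estimated correlation), including ADAM19 (2.58 (SE 0.17)), the matrilysin gene MMP7 (1.51 (SE 0.101)) and the urokinase gene PLAU (1.23 (SE 0.104)). In the extracellular matrix and basement membrane list 10 rose and 4 fell of 24 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00396, adjusted p = 0.498 with an estimated correlation), and LAMB3 rose by 2.11 (SE 0.117). The mesenchymal list had 9 of 23 higher and none lower (11 and 1 adjusted over the list alone; camera adjusted p = 7.63e-05, adjusted p = 0.498 with an estimated correlation), led by the matrix protein gene TNC (2.42 (SE 0.158)), the collagen cross-linking enzyme gene LOXL2 (1.33 (SE 0.117)) and SPARC (1.66 (SE 0.157)). TGF-beta targets had 9 of 20 higher and none lower (13 adjusted over the list alone; camera adjusted p = 1.63e-06, adjusted p = 0.405 with an estimated correlation), among them PMEPA1 (1.80 (SE 0.102)).

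WNT targets had 6 of 15 higher and none lower (10 adjusted over the list alone; camera adjusted p = 1.42e-05, adjusted p = 0.249 with an estimated correlation). NKD1 stood at 1.58 (SE 0.124) and TNFRSF19 at 1.38 (SE 0.205). Secreted growth and angiogenic factors had 9 higher and 1 lower of 20 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00244, adjusted p = 0.447 with an estimated correlation). Apart from CXCL8, they included the EGF receptor ligand gene EREG (1.34 (SE 0.136)), NRG1 (0.98 (SE 0.114)) and ANGPTL4 (1.39 (SE 0.179)). The MAPK output list had 7 higher and 1 lower of 22 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00839, adjusted p = 0.456 with an estimated correlation). The AP-1 subunit gene FOSL1 stood at 0.93 (SE 0.155) and MYC at 0.54 (SE 0.102). In the order without WT replicate 1, WT replicate 2, T133A replicate 1, T133A replicate 2, KO replicate 1 and KO replicate 2, the numbers called higher were 5, 5, 6, 10, 10 and 10 for secreted factors, 5, 5, 8, 10, 11 and 11 for TGF-beta targets and 5, 4, 7, 8, 7 and 7 for MAPK output. The number called lower in the matrix list was 1 without WT replicate 1 and 2 without WT replicate 2, and the 1 lower in the MAPK list was lost without either WT library and without T133A replicate 1.

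Glycolysis genes had 8 of 20 higher and none lower (11 adjusted over the list alone; camera adjusted p = 7.63e-05, adjusted p = 0.636 with an estimated correlation). The phosphofructokinase gene PFKP stood at 0.57 (SE 0.107) and PFKFB3 at 0.56 (SE 0.106). Hypoxia targets had 7 of 21 higher and none lower (12 adjusted over the list alone; camera adjusted p = 1.64e-05, adjusted p = 0.249 with an estimated correlation), and ATF4 targets 6 of 28 higher and none lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.00839, adjusted p = 0.498 with an estimated correlation); STC2, a secreted glycoprotein gene in both lists, rose by 1.33 (SE 0.14). Antigen presentation genes had 4 of 19 higher (8 adjusted over the list alone; camera adjusted p = 0.00209, adjusted p = 0.498 with an estimated correlation). The class I heavy chain gene HLA-B stood at 0.88 (SE 0.106), whose reads may be shared with other HLA genes. Cytosolic ribosomal proteins (3 of 34 higher, 2 adjusted over the list alone; camera adjusted p = 5.77e-04, adjusted p = 0.667 with an estimated correlation) and mitochondrially encoded genes (1 of 13 higher, 5 adjusted over the list alone; camera adjusted p = 0.00839, adjusted p = 0.667 with an estimated correlation) passed with medians of only 0.17 and 0.27. Their members RPLP2 (log2 fold change 0.39, adjusted p = 0.0124) and MT-ND4L (log2 fold change 0.47, adjusted p = 0.017) lost their calls without either WT library, and without T133A replicate 1 both list calls were lost (adjusted p = 0.105 and 0.0617). In the order without WT replicate 1, WT replicate 2, T133A replicate 1, T133A replicate 2, KO replicate 1 and KO replicate 2, the numbers called higher were 2, 2, 4, 12, 8 and 8 for glycolysis, 2, 2, 4, 10, 9 and 8 for hypoxia targets, 3, 3, 4, 9, 8 and 8 for ATF4 targets, 1, 3, 2, 8, 5 and 5 for antigen presentation, 0, 0, 3, 20, 7 and 6 for ribosomal proteins and 0, 0, 1, 3, 7 and 7 for mitochondrially encoded genes. With the GC and length correction they were 8 for antigen presentation, 9 for ribosomal proteins and 3 for mitochondrially encoded genes. T133A carried more mitochondrial counts (8.91% and 8.51% against 7.87% and 7.84% in WT), and its fold changes rose with GC content across genes (Spearman's rho 0.23), as did the difference between the T133A replicates (0.69).

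The lists lower in T133A by camera were mitosis, NRF2 targets, cholesterol synthesis and interferon response. With fry, NRF2 targets (adjusted p = 0.071) and cholesterol synthesis (adjusted p = 0.162) did not pass. Mitosis genes had 8 of 32 lower and none higher (10 adjusted over the list alone; camera adjusted p = 0.00244, adjusted p = 0.249 with an estimated correlation), including the kinetochore genes CENPF (-0.67 (SE 0.112)) and CENPE (-0.71 (SE 0.136)). NRF2 targets, genes of the antioxidant response, had 7 of 27 lower and none higher (16 adjusted over the list alone; camera adjusted p = 4.33e-06, adjusted p = 0.498 with an estimated correlation). OSGIN1 stood at -1.10 (SE 0.136) and the reductase gene AKR1B10 at -0.76 (SE 0.106). Cholesterol synthesis had 4 of 25 lower and none higher (10 adjusted over the list alone; camera adjusted p = 8.86e-05, adjusted p = 0.498 with an estimated correlation). HMGCS1, an early enzyme of the pathway, stood at -0.65 (SE 0.114). In the interferon response list 6 fell and 1 rose of 36 (the same counts adjusted over the list alone; camera adjusted p = 0.00839, adjusted p = 0.249 with an estimated correlation), among them IFI44L (-0.60 (SE 0.111)) and DDX60 (-0.62 (SE 0.133)), and this call was lost without T133A replicate 2 (adjusted p = 0.0839). In the order without WT replicate 1, WT replicate 2, T133A replicate 1, T133A replicate 2, KO replicate 1 and KO replicate 2, the numbers called lower were 3, 3, 4, 12, 8 and 8 for mitosis, 4, 4, 11, 8, 16 and 16 for NRF2 targets, 3, 5, 1, 5, 10 and 10 for cholesterol synthesis and 3, 4, 5, 9, 8 and 8 for interferon response. With the GC and length correction they were 16 for NRF2 targets, 9 for cholesterol synthesis and 13 for interferon response.

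The other lists did not pass in this comparison by camera. Lung epithelial lineage genes had 0 higher and 4 lower of 17 (adjusted p = 0.0697), including the mucin genes MUC5AC (-1.24 (SE 0.105)) and MUC5B (-1.04 (SE 0.129)); the list passed without T133A replicate 1 (adjusted p = 0.00406) and with the GC and length correction (0.0333), where the HOXB cluster (0 higher and 0 lower of 9 (adjusted p = 0.103)) passed too (0.0467 and 0.0333). Lysosome and autophagy genes had 5 higher and 0 lower of 28 (adjusted p = 0.291). The cathepsin gene CTSS stood at 1.11 (SE 0.105), and the list passed without T133A replicate 2 (0.0487). The epithelial junction list had 3 higher and 2 lower of 23 (adjusted p = 0.722). CLDN1 stood at 0.79 (SE 0.12). The stemness and drug resistance list had 5 higher and 3 lower of 21 (adjusted p = 0.88). The Notch ligand gene JAG1 stood at 0.92 (SE 0.108). Fatty acid synthesis had 3 higher and 3 lower of 22 (adjusted p = 0.29). ACSL3 stood at -0.56 (SE 0.106). The HOXA, HOXC and HOXD clusters had 2 higher and 0 lower of 19 (adjusted p = 0.309), p53 targets 2 higher and 0 lower of 27 (adjusted p = 0.771), fatty acid oxidation 0 higher and 1 lower of 22 (adjusted p = 0.291), the unfolded protein response 0 higher and 1 lower of 19 (adjusted p = 0.88) and nuclear oxidative phosphorylation 0 higher and 1 lower of 32 (adjusted p = 0.472). The immediate early and heat shock list had 2 higher and 3 lower of 18 (adjusted p = 0.67). KLF2 stood at -1.42 (SE 0.205). No member of the DNA replication list passed (34 tested, adjusted p = 0.583), where PCNA stood at 0.08 (SE 0.0977). With the libraries left out in that same order, the numbers called lower were 0, 0, 3, 0, 3 and 3 for epithelial junctions, 3, 3, 2, 3, 8 and 8 for fatty acid synthesis, 2, 3, 4, 4, 4 and 4 for lung lineage, 2, 2, 2, 3, 4 and 4 for stemness and 2, 2, 3, 4, 3 and 3 for immediate early genes, and those called higher 1, 1, 2, 2, 3 and 3 for fatty acid synthesis, 3, 4, 4, 5, 5 and 5 for lysosome and autophagy, 3, 3, 4, 5, 5 and 5 for stemness and 0, 1, 2, 5, 3 and 3 for p53 targets. With the GC and length correction those lower were 5 for epithelial junctions, 6 for fatty acid synthesis, 5 for stemness and 5 for immediate early genes, and 4 p53 targets were higher. Lysosome and autophagy then had 3 lower, and nuclear oxidative phosphorylation 3 lower. Counts of 1 or 2 members of a list also changed with single libraries and with this correction.

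Of the markers of other cells, none of 3 fibroblast markers (adjusted p = 0.88) and none of 8 embryonic kidney line markers (adjusted p = 0.88) passed in T133A against WT. The haematopoietic and endothelial lists had only 2 measured members each and were not tested as lists. ITGAM passed (log2 fold change 1.40, adjusted p = 0.00468) but not without T133A replicate 1, and EGFL7 stood at 0.04 (SE 0.131). Median, mean and test differed in sign for the stemness list (median -0.03, mean 0.03, test up), the unfolded protein response (0.01, -0.01, down), fibroblast markers (0.11, -0.06, up) and embryonic kidney line markers (-0.05, 0.01, down).

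The comparison of KO with WT asked which transcripts differ between cells labelled as a HOXB9 knockout and cells given HOXB9. With no empty-vector or untreated group, effects of added HOXB9 and of its loss could not be told apart. CEACAM5, which encodes carcinoembryonic antigen, stood at 282 ± 3.21 CPM in WT and was counted only 2 times over both KO libraries, a ratio of 4942 with a 95% counting interval of 1368 to 40809 (adjusted p = 5.61e-20; ENSG00000105388, chromosome 19, 41708585 to 41729798). TM4SF20, a tetraspanning membrane protein gene, fell from 584 ± 3.19 to 1.3 ± 0.293 CPM (log2 fold change -8.79, SE 0.164, adjusted p = 1.25e-20), and FGB, the fibrinogen beta chain gene, from 141 ± 2.85 to 0.613 ± 0.351 CPM (log2 fold change -7.80, SE 0.196, adjusted p = 7.99e-19). In the other direction KCNMA1, a calcium-activated potassium channel gene, rose from 2.37 ± 0.20 to 77.3 ± 3.07 CPM (log2 fold change 5.02, SE 0.165, adjusted p = 1.19e-16), and HAS3, a hyaluronan synthase gene, from 8.2 ± 0.938 to 119.7 ± 13.9 CPM (log2 fold change 3.86, SE 0.142, adjusted p = 9.43e-16).

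MYO7B, a myosin of microvilli, HGF, the hepatocyte growth factor gene, REG4 and the amino-acid receptor gene GPRC6A had 0 counts in both KO libraries against 291, 197, 186 and 185 in WT. They were at least 48.3-, 32.7-, 30.9- and 30.7-fold lower, taking 3 counts per library as the floor. COL3A1, a fibrillar collagen gene, had 2 counts (a ratio of 235 with a 95% counting interval of 64.6 to 1943), and the amino-acid transporter gene SLC6A20 had 1 count (a ratio of 223 with a 95% counting interval of 39.6 to 8851). MUC16, a membrane mucin, fell from 55.2 ± 2.89 to 0.303 ± 0.257 CPM (log2 fold change -7.43 (SE 0.25)). The other large rises were in CCBE1, a secreted matrix protein gene with 1 count in WT and 213 in KO (a ratio of 213 with a 95% counting interval of 37.8 to 8449), RRAD, a small GTPase gene (6.78 (SE 0.416)), OLFML3 (4.34 (SE 0.236)), SYT6 (4.67 (SE 0.299)), RNF182 (4.66 (SE 0.341)), LYPD1 (4.33 (SE 0.294)), MARCHF4 (4.04 (SE 0.287)) and SNAI2, which encodes the transcriptional repressor Slug (4.39 (SE 0.431)). All of these 20 genes passed edgeR's test. CEACAM5, CEACAM6 and CEACAM7 are similar in sequence and may share reads.

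**Figure D3:**
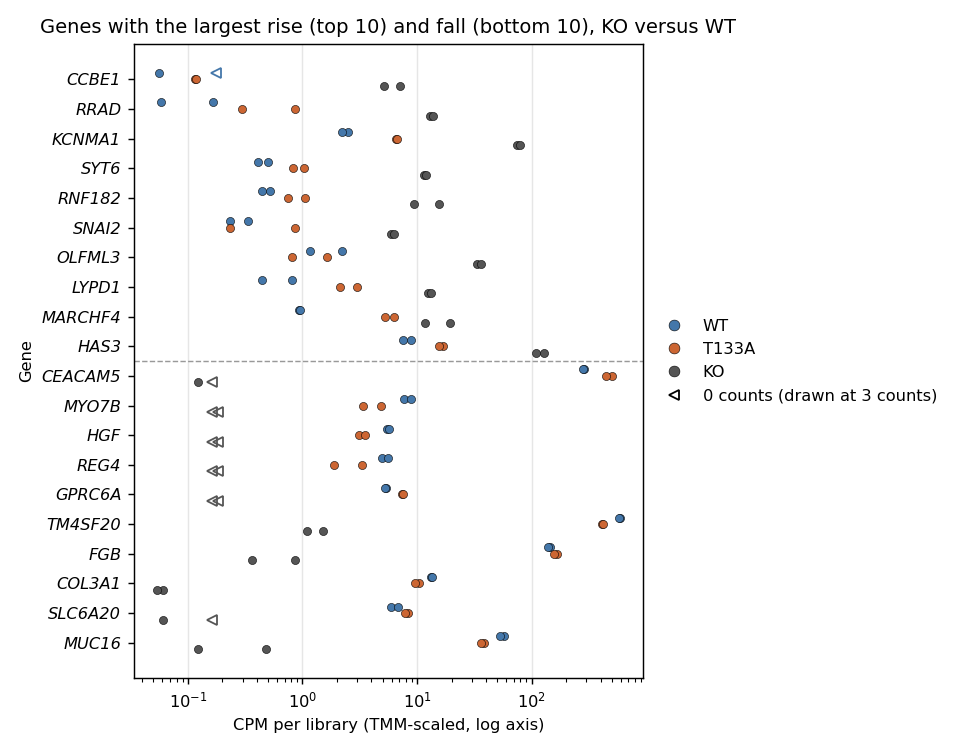
CPM in each library (horizontal log axis, TMM-scaled) of the 10 genes with the largest rise and the 10 with the largest fall in KO against WT; points are libraries and open triangles stand for libraries with 0 counts, drawn at the level of 3 counts. CEACAM5 averages 282 CPM in WT, and KCNMA1 77.3 CPM in KO against 2.37 CPM in WT.

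edgeR called 7622 genes, 46.6% of those tested, 3862 higher and 3760 lower in KO. Differences of at least 1 on the log2 scale were mostly falls, 1733 lower against 757 higher. The number higher was 2563 without WT replicate 1.

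Interferon response genes fell almost without exception. Of 36 members tested, 35 fell and none rose (35 adjusted over the list alone), with a median log2 fold change of -1.77 (camera adjusted p = 1.14e-17, adjusted p = 0.0624 with an estimated correlation). BST2, which encodes tetherin, fell from 112 ± 8.29 to 4.8 ± 0.933 CPM (log2 fold change -4.55, SE 0.145, adjusted p = 7.01e-17), IFI27 from 531 ± 33.4 to 40.3 ± 0.565 CPM (log2 fold change -3.72, SE 0.118, adjusted p = 7.01e-17), and OAS2, a sensor of double-stranded RNA, from 429 ± 6.06 to 38.03 ± 3.22 CPM (log2 fold change -3.49 (SE 0.112)). Antigen presentation genes followed with 14 lower and 2 higher of 19 (the same counts adjusted over the list alone; camera adjusted p = 1.82e-04, adjusted p = 0.445 with an estimated correlation). HLA-B fell from 185 ± 9.91 to 36.97 ± 0.519 CPM and B2M, the class I light chain gene, from 1322 ± 50.7 to 418 ± 30.9 CPM (log2 fold change -2.32 (SE 0.114) and -1.66 (SE 0.107)).

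Lung epithelial lineage genes fell in 12 of 17 and rose in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 8.82e-06, adjusted p = 0.388 with an estimated correlation). The gel-forming mucin gene MUC5AC fell from 1338 ± 79.1 to 12.5 ± 0.306 CPM (log2 fold change -6.74, SE 0.138, adjusted p = 4.96e-20), MUC5B from 2926 ± 122 to 59.4 ± 8.59 CPM, the basal cell regulator TP63 from 31.6 ± 1.46 to 0.795 ± 0.0938 CPM, and the pioneer factor FOXA1 from 83.7 ± 7.83 to 18.3 ± 0.462 CPM. Epithelial junction genes fell in 14 and rose in 2 of 23 (16 and 2 adjusted over the list alone; camera adjusted p = 0.00131, adjusted p = 0.379 with an estimated correlation), including the adhesion molecule gene EPCAM (-3.10 (SE 0.208)), the plakoglobin gene JUP (-2.20 (SE 0.127)) and the claudin genes CLDN2 (-2.63 (SE 0.121)) and CLDN4 (-2.52 (SE 0.193)). The stemness and drug resistance list fell in 14 and rose in 4 of 21 (the same counts adjusted over the list alone; camera adjusted p = 0.00445, adjusted p = 0.275 with an estimated correlation). The drug efflux pump gene ABCG2 stood at -2.08 (SE 0.108) and the receptor gene LGR6 at -2.48 (SE 0.145). The unfolded protein response fell in 14 and rose in 1 of 19 (the same counts adjusted over the list alone; camera adjusted p = 8.31e-04, adjusted p = 0.402 with an estimated correlation). Its transcription factor XBP1 stood at -1.05 (SE 0.114) and the chaperone gene HSP90B1 at -0.86 (SE 0.108).

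All 9 HOXB genes tested fell in KO (median log2 fold change -1.61; 9 lower adjusted over the list alone; camera adjusted p = 6.89e-05, adjusted p = 0.251 with an estimated correlation). HOXB9 fell the most. HOXB2 stood at -2.45, HOXB3 at -1.81, HOXB6 at -1.62, HOXB4 at -1.61, HOXB5 at -1.45, HOXB8 at -1.02, HOXB13 at -0.58 and HOXB7 at -0.48. Without KO replicate 1, 6 of them passed. The cluster spans 48528526 to 48729178 on chromosome 17, and among 22 flanking protein-coding genes within 1 Mb at 5 CPM or more, the median was 0.14 (quartiles -0.27 and 0.31), with 5 lower and 7 higher. SKAP1 (-3.35) and TTLL6 (-2.74), the nearest measured coding genes on either side, were lower in KO, as were PRR15L (-3.39) and CDK5RAP3 (-1.58), while ATP5MC1 (0.72) was higher. SKAP1 stood at only 1.23 CPM in WT and 0.118 CPM in KO, and PRR15L at 4.54 and 0.421 CPM. Both lay under the 5 CPM minimum and were not among the 22 flanking genes. The HOXB genes other than HOXB3, HOXB5, HOXB6 and HOXB9, and the flanking genes, were picked out after their values were seen.

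**Figure D4:**
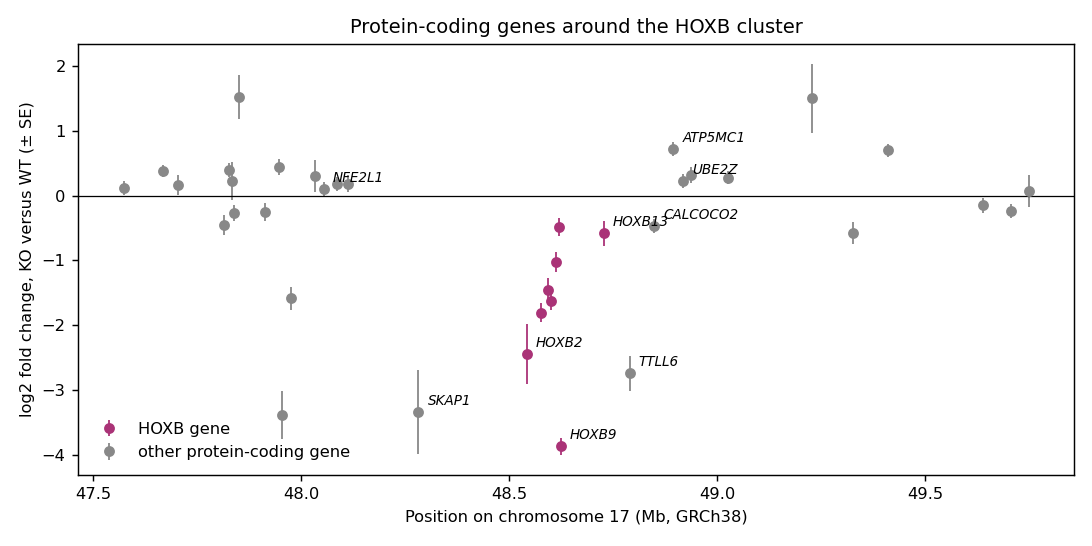
Log2 fold change, KO against WT (vertical axis, points with SE from 2 libraries per group), of protein-coding genes by position on chromosome 17 (horizontal axis, Mb, GRCh38) around the HOXB cluster. The HOXB genes drawn, in purple, all lie below 0, from -0.48 to -3.88, and SKAP1 and TTLL6 on either side lie at -3.35 and -2.74. Genes of low mean level, HOXB4 among them, are not drawn.

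Genes of growth and of the p53 response rose in KO. Of the p53 targets 22 of 27 rose and none fell (22 adjusted over the list alone; camera adjusted p = 8.16e-07, adjusted p = 0.154 with an estimated correlation), including the cell cycle inhibitor gene CDKN1A (1.19 (SE 0.104)) and the pro-apoptotic gene BAX (1.21 (SE 0.108)). DNA replication genes rose in 24 of 34 and none fell (25 adjusted over the list alone; camera adjusted p = 5.33e-07, adjusted p = 0.379 with an estimated correlation). The origin licensing gene CDT1 stood at 0.94 (SE 0.119) and the helicase subunit gene MCM5 at 0.78 (SE 0.108). Mitosis genes rose in 17 and fell in 2 of 32 (the same counts adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.251 with an estimated correlation). CDC20 stood at 1.33 (SE 0.108) and PLK1 at 1.06 (SE 0.109). ATF4 targets rose in 19 and fell in 2 of 28 (20 and 2 adjusted over the list alone; camera adjusted p = 2.82e-04, adjusted p = 0.402 with an estimated correlation), where STC2 went from 7.27 ± 0.283 to 101 ± 0.979 CPM and the serine synthesis gene PSAT1 rose by 1.41 (SE 0.102), while CTH, an enzyme of cysteine synthesis, stood at -2.63 (SE 0.175). Glycolysis genes rose in 11 and fell in 1 of 20 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00491, adjusted p = 0.732 with an estimated correlation). PFKFB3 stood at 1.46 (SE 0.108) and the lactate exporter gene SLC16A3 at -0.91 (SE 0.122). The glycolysis call was lost with the GC and length correction (adjusted p = 0.0514).

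All 34 cytosolic ribosomal protein genes tested were higher in KO (34 adjusted over the list alone; median log2 fold change 0.66; camera adjusted p = 5.54e-11, adjusted p = 0.445 with an estimated correlation). RPS2 stood at 1.07 (SE 0.109) and RPL18 at 0.97 (SE 0.11). Nuclear genes of oxidative phosphorylation rose in 14 of 32 and none fell (14 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.629 with an estimated correlation), including CYC1 (0.82 (SE 0.106)). Mitochondrially encoded genes fell in 10 and rose in 1 of 13 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00475, adjusted p = 0.663 with an estimated correlation). MT-ND5 stood at -1.28 (SE 0.126) and MT-CO1 at -0.99 (SE 0.139). All genes of the mitochondrial genome, its rRNA genes included, took 5.60% and 4.45% of the counts in KO against 7.87% and 7.84% in WT. Fold changes of KO against WT rose with GC content (Spearman's rho 0.32 across genes) and fell with length (-0.27), and after correcting for both 30 ribosomal genes stayed higher. Nuclear oxidative phosphorylation then had 12 genes higher and 1 lower, with 7 of the 14 among those higher, and its median went from 0.27 to 0.08. In the order without WT replicate 1, WT replicate 2, T133A replicate 1, T133A replicate 2, KO replicate 1 and KO replicate 2, the numbers called higher were 11, 11, 19, 19, 15 and 17 for mitosis and 7, 8, 17, 20, 15 and 10 for nuclear oxidative phosphorylation.

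The NF-kB and inflammatory cytokine list was mixed in KO, with 12 higher and 7 lower of 25 (the same counts adjusted over the list alone). PTGS2, which encodes cyclooxygenase-2, fell from 548 ± 37.3 to 46.6 ± 10.2 CPM (log2 fold change -3.55, SE 0.137, adjusted p = 2.09e-15), and CXCL5 and CXCL1 fell by 2.47 and 2.55 on the log2 scale (SE 0.116 and 0.123), while RELB, an NF-kB subunit gene named after its value was seen, rose by 1.55 (SE 0.156). The list's median was 0.56 and its mean -0.26, camera gave no call (up, adjusted p = 0.56), and the rotation test fry gave a fall (adjusted p = 0.00422).

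Other lists also moved in both directions and did not pass by camera. Secreted growth factors had 12 higher and 6 lower of 20 (adjusted p = 0.145). NRG1 stood at 2.03 (SE 0.114), EREG at 1.41 (SE 0.136) and CXCL8 at -1.93 (SE 0.194). Mesenchymal genes had 11 higher and 6 lower of 23 (adjusted p = 0.308). SPARC stood at 2.93 (SE 0.156) and the fibronectin gene FN1 at -1.62 (SE 0.111). Matrix and basement membrane genes had 8 higher and 11 lower of 24 (adjusted p = 0.649). The collagen VI gene COL6A2 stood at 2.40 (SE 0.158) and COL12A1 at -2.58 (SE 0.108). Integrins and proteases had 5 higher and 9 lower of 23 (adjusted p = 0.308). PLAU stood at 1.89 (SE 0.105) and MMP7 at -1.71 (SE 0.105). MAPK output had 6 higher and 9 lower of 22 (adjusted p = 0.308). FOSL1 stood at 3.44 (SE 0.149) and FOS at -3.12 (SE 0.187). WNT targets had 4 higher and 8 lower of 15 (adjusted p = 0.308). The WNT antagonist gene DKK1 stood at -2.91 (SE 0.114). TGF-beta targets had 10 higher and 6 lower of 20 (adjusted p = 0.493). LTBP1 stood at -2.42 (SE 0.112). NRF2 targets had 11 higher and 11 lower of 27 (adjusted p = 0.794). The haem oxygenase gene HMOX1 stood at 2.40 (SE 0.144) and AKR1C1 at -2.09 (SE 0.124), whose reads may be shared with AKR1C2 and AKR1C3. Secreted factors passed with no low-count filter (adjusted p = 0.0353) and WNT targets among genes of at least 5 CPM (0.0479).

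In the same comparison hypoxia targets had 5 higher and 8 lower of 21 (adjusted p = 0.577), cholesterol synthesis 4 higher and 9 lower of 25 (adjusted p = 0.56), fatty acid synthesis 4 higher and 7 lower of 22 (adjusted p = 0.4) and fatty acid oxidation 5 higher and 7 lower of 22 (adjusted p = 0.56). PDK4 stood at -2.73 (SE 0.114). Lysosome and autophagy had 7 higher and 7 lower of 28 (adjusted p = 0.619). CTSS stood at -1.59 (SE 0.11). The immediate early and heat shock list had 9 higher and 4 lower of 18 (adjusted p = 0.308). The nuclear receptor gene NR4A2 stood at -3.91 (SE 0.192) and the chaperone partner gene BAG3 at 1.05 (SE 0.109); the list's median was 0.50 and its mean -0.02, and the test pointed up. The HOXA, HOXC and HOXD clusters had 4 higher and 3 lower of 19 (adjusted p = 0.619). HOXC6 stood at -1.97 (SE 0.18) and HOXA13 at -1.29 (SE 0.189); without WT replicate 2 no member was higher, and none with the GC and length correction. Among fibroblast markers, 1 rose and 2 fell of 3 (adjusted p = 0.335), where the proteoglycan gene LUM went from 21.3 ± 0.506 to 0.229 ± 0.0195 CPM. Embryonic kidney line markers had 4 higher and 1 lower of 8 (adjusted p = 0.168). SALL4 stood at -2.17 (SE 0.261). PECAM1 of the endothelial list had 27 counts in WT and 1 in KO (a ratio of 27.01 with a 95% counting interval of 4.45 to 1106), and ITGAM of the haematopoietic list rose from 1.32 ± 0.205 to 5.29 ± 0.41 CPM.

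Counts of list members in KO against WT also changed when single libraries were left out, which leaves 1 library in a group where that library is WT or KO. With the libraries left out in turn, from WT replicate 1 to KO replicate 2 as before, the numbers called higher were 3, 2, 5, 6, 7 and 1 for cholesterol synthesis, 2, 2, 4, 4, 5 and 2 for fatty acid synthesis, 1, 2, 7, 7, 6 and 1 for fatty acid oxidation, 4, 4, 7, 8, 9 and 4 for lysosome and autophagy, 4, 3, 4, 4, 4 and 2 for stemness, 2, 3, 5, 5, 4 and 2 for kidney line markers and 3, 0, 4, 5, 3 and 2 for the HOXA, HOXC and HOXD clusters. Those called lower were 6, 7, 11, 11, 9 and 10 for NRF2 targets, 5, 7, 8, 8, 7 and 5 for hypoxia targets, 7, 6, 10, 10, 7 and 11 for lysosome and autophagy and 3, 2, 3, 4, 4 and 2 for the HOXA, HOXC and HOXD clusters. With the GC and length correction 1 gene of cholesterol synthesis and 3 of fatty acid oxidation were higher, and 12 of lysosome and autophagy, 5 of the HOXA, HOXC and HOXD clusters, 4 ATF4 targets and 3 of glycolysis lower.

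The comparison of T133A with KO asked how cells carrying the changed HOXB9 differ from cells labelled as its knockout. CEACAM5 stood at 472 ± 40.4 CPM in T133A against 2 counts over both KO libraries (a ratio of 8283 with a 95% counting interval of 2292 to 68398; adjusted p = 2.09e-20), and CXCL1 at 639 ± 29.6 against 8.44 ± 0.17 CPM (log2 fold change 6.24, SE 0.13, adjusted p = 4.55e-20). TM4SF20 (416 ± 9.6 against 1.3 ± 0.293 CPM) and FGB (161 ± 6.61 against 0.613 ± 0.351 CPM) were higher in T133A by 8.30 (SE 0.163) and 7.99 (SE 0.195) on the log2 scale. KCNMA1 (6.6 ± 0.146 against 77.3 ± 3.07 CPM; log2 fold change -3.55, SE 0.144, adjusted p = 4.85e-15) and SNAI2 (-3.46 (SE 0.386)) were lower.

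GPR141, an orphan receptor gene, PPBP, a platelet chemokine gene, GPRC6A and the amino-acid transporter gene SLC6A14 had 321, 273, 256 and 209 counts in T133A and 0 in KO, so they were at least 54.3-, 46.1-, 43.3- and 35.4-fold higher. SERPINB3 and CEACAM7 had 1 count each in KO (a ratio of 3094 with a 95% counting interval of 555 to 122229, and a ratio of 529 with a 95% counting interval of 94.5 to 20928), and CCL20 had 2 (a ratio of 282 with a 95% counting interval of 77.8 to 2336). The largest falls also included OLFML3 (-4.82 (SE 0.25)), CCBE1 (-5.63 (SE 0.484)), RRAD (-4.51 (SE 0.318)), RNF182 (-3.78 (SE 0.308)), SYT6 (-3.65 (SE 0.266)), AMPH (-3.38 (SE 0.393)), KIRREL3 (-3.32 (SE 0.251)) and PADI3, an enzyme that converts arginine to citrulline (-3.06 (SE 0.20)). edgeR called 6523 genes, 3322 higher and 3201 lower in T133A, and of 2097 differing by at least 1 on the log2 scale 1509 were higher.

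Immune and epithelial lists were higher in T133A than in KO. All 36 interferon response genes tested were higher (36 adjusted over the list alone; camera adjusted p = 8.62e-19, adjusted p = 0.057 with an estimated correlation). BST2 stood at 4.66 (SE 0.145). The NF-kB and cytokine list had 19 higher and 0 lower of 25 (19 and 1 adjusted over the list alone; camera adjusted p = 6.77e-10, adjusted p = 0.141 with an estimated correlation), with CXCL5 at 5290.5 ± 483 against 140.1 ± 6.25 CPM. Antigen presentation had 15 higher and 0 lower of 19 (15 and 1 adjusted over the list alone; camera adjusted p = 2.85e-06, adjusted p = 0.292 with an estimated correlation). HLA-B stood at 3.20 (SE 0.117). Lung epithelial lineage had 11 higher and 2 lower of 17 (13 and 2 adjusted over the list alone; camera adjusted p = 6.16e-06, adjusted p = 0.285 with an estimated correlation). MUC5AC stood at 5.49 (SE 0.132). Epithelial junctions had 13 higher and 3 lower of 23 (the same adjusted over the list alone; camera adjusted p = 8.04e-04, adjusted p = 0.28 with an estimated correlation). JUP stood at 2.37 (SE 0.127). The stemness and drug resistance list had 15 higher and 4 lower of 21 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.182 with an estimated correlation). The ligand gene BMP4 stood at 2.36 (SE 0.119). The HOXB cluster had 7 higher and 0 lower of 9 (8 and 0 adjusted over the list alone; camera adjusted p = 1.36e-04, adjusted p = 0.182 with an estimated correlation). HOXB6 stood at 1.46 (SE 0.154).

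WNT targets had 10 higher and 2 lower of 15 (11 and 2 adjusted over the list alone; camera adjusted p = 7.67e-04, adjusted p = 0.28 with an estimated correlation). DKK1 stood at 3.20 (SE 0.115) and AXIN2 at 1.87 (SE 0.153). Integrins and proteases had 13 higher and 4 lower of 23 (the same adjusted over the list alone; camera adjusted p = 0.00286, adjusted p = 0.182 with an estimated correlation). MMP7 stood at 3.22 (SE 0.11). MAPK output had 11 higher and 3 lower of 22 (the same adjusted over the list alone; camera adjusted p = 0.00691, adjusted p = 0.292 with an estimated correlation). EMP1 stood at 2.08 (SE 0.135) and FOSL1 at -2.51 (SE 0.139). The unfolded protein response had 14 higher and 1 lower of 19 (15 and 1 adjusted over the list alone; camera adjusted p = 2.32e-04, adjusted p = 0.286 with an estimated correlation). XBP1 stood at 0.82 (SE 0.114). Matrix and basement membrane genes had 14 higher and 5 lower of 24 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0304, adjusted p = 0.436 with an estimated correlation). LAMB3 stood at 2.91 (SE 0.122). Hypoxia targets had 11 higher and 3 lower of 21 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0208, adjusted p = 0.358 with an estimated correlation). CA12 stood at 1.48 (SE 0.12). Both of these last calls were lost without T133A replicate 1 (adjusted p = 0.0809 for each), and the matrix call with the GC and length correction (0.0551). Mitochondrially encoded genes had 11 higher and 1 lower of 13 (the same adjusted over the list alone; camera adjusted p = 2.32e-04, adjusted p = 0.436 with an estimated correlation). MT-ND5 stood at 1.41 (SE 0.127), in libraries whose mitochondrial shares were 8.91% and 8.51% against 5.60% and 4.45%.

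Lists of cell cycle, p53 target, ribosomal protein, nuclear oxidative phosphorylation, ATF4 target and NRF2 target genes were lower in T133A than in KO. Mitosis had 0 higher and 26 lower of 32 (0 and 27 adjusted over the list alone; camera adjusted p = 1.08e-07, adjusted p = 0.0948 with an estimated correlation). CDC20 stood at -1.25 (SE 0.108). DNA replication had 0 higher and 26 lower of 34 (the same adjusted over the list alone; camera adjusted p = 1.08e-07, adjusted p = 0.28 with an estimated correlation). The thymidylate synthase gene TYMS stood at -1.02 (SE 0.128). The p53 targets had 0 higher and 20 lower of 27 (1 and 21 adjusted over the list alone; camera adjusted p = 2.28e-07, adjusted p = 0.0948 with an estimated correlation). BAX stood at -1.03 (SE 0.108). Ribosomal proteins had 0 higher and 32 lower of 34 (the same adjusted over the list alone; camera adjusted p = 2.71e-09, adjusted p = 0.369 with an estimated correlation). RPL13 stood at -0.90 (SE 0.11). Nuclear oxidative phosphorylation had 0 higher and 18 lower of 32 (the same adjusted over the list alone; camera adjusted p = 1.25e-04, adjusted p = 0.436 with an estimated correlation). CYC1 stood at -0.77 (SE 0.106). The number lower in the latter was 11 without T133A replicate 2. ATF4 targets had 3 higher and 13 lower of 28 (3 and 14 adjusted over the list alone; camera adjusted p = 0.00468, adjusted p = 0.369 with an estimated correlation). SLC7A5, an amino-acid transporter gene, stood at -1.19 (SE 0.108). NRF2 targets had 5 higher and 15 lower of 27 (the same adjusted over the list alone; camera adjusted p = 0.0207, adjusted p = 0.59 with an estimated correlation). HMOX1 stood at -2.85 (SE 0.147), and the list lost its call without KO replicate 2 (adjusted p = 0.0572). Fold changes between these groups fell with GC content (Spearman's rho -0.22 across genes).

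The lists without a camera call between T133A and KO were TGF-beta targets with 11 higher and 4 lower of 20 (adjusted p = 0.0537), secreted factors with 6 higher and 8 lower of 20 (adjusted p = 0.663), mesenchymal genes with 9 higher and 8 lower of 23 (adjusted p = 0.474), glycolysis with 4 higher and 8 lower of 20 (adjusted p = 0.441), cholesterol synthesis with 5 higher and 9 lower of 25 (adjusted p = 0.156), fatty acid synthesis with 5 higher and 6 lower of 22 (adjusted p = 0.767), fatty acid oxidation with 5 higher and 4 lower of 22 (adjusted p = 0.832) and lysosome and autophagy with 9 higher and 5 lower of 28 (adjusted p = 0.27). TGF-beta targets passed with the GC and length correction (adjusted p = 0.00869), with no low-count filter (0.0264), among genes of at least 5 CPM (0.0320), without T133A replicate 2 (0.0269) and without KO replicate 1 (0.0302). Cholesterol synthesis passed without KO replicate 1 (0.00821) and lysosome and autophagy without KO replicate 2 (0.0382). The HOXA, HOXC and HOXD clusters had 3 higher and 3 lower of 19 (adjusted p = 0.75), immediate early and heat shock genes 5 higher and 10 lower of 18 (adjusted p = 0.253), fibroblast markers 2 higher and 1 lower of 3 (adjusted p = 0.27) and embryonic kidney line markers 1 higher and 3 lower of 8 (adjusted p = 0.0999), which passed with no low-count filter (0.0497). Of the lists not tested, endothelial PECAM1 had 58 counts in T133A and 1 in KO (a ratio of 59.1 with a 95% counting interval of 10.2 to 2374), and haematopoietic CD14 stood at 0.56 (SE 0.246) (adjusted p = 0.0802). Median and mean differed in sign for secreted factors (-0.08 and 0.24, test down) and fatty acid oxidation (-0.02 and 0.18, test up). As each library was left out in the order given before, the numbers called higher were 6, 6, 1, 3, 2 and 7 for cholesterol synthesis and 6, 6, 5, 5, 4 and 9 for fatty acid synthesis, and those called lower 8, 8, 6, 5, 6 and 6 for secreted factors, 4, 4, 4, 4, 5 and 2 for integrins and proteases, 6, 6, 6, 6, 7 and 3 for fatty acid synthesis, 4, 4, 5, 3, 8 and 2 for lysosome and autophagy and 2, 2, 3, 0, 3 and 1 for the HOXA, HOXC and HOXD clusters. With the GC and length correction 7 genes of glycolysis, 8 NRF2 targets, 5 ATF4 targets and 5 of the HOXA, HOXC and HOXD clusters were higher, and 3 of lysosome and autophagy lower.

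**Figure D5:**
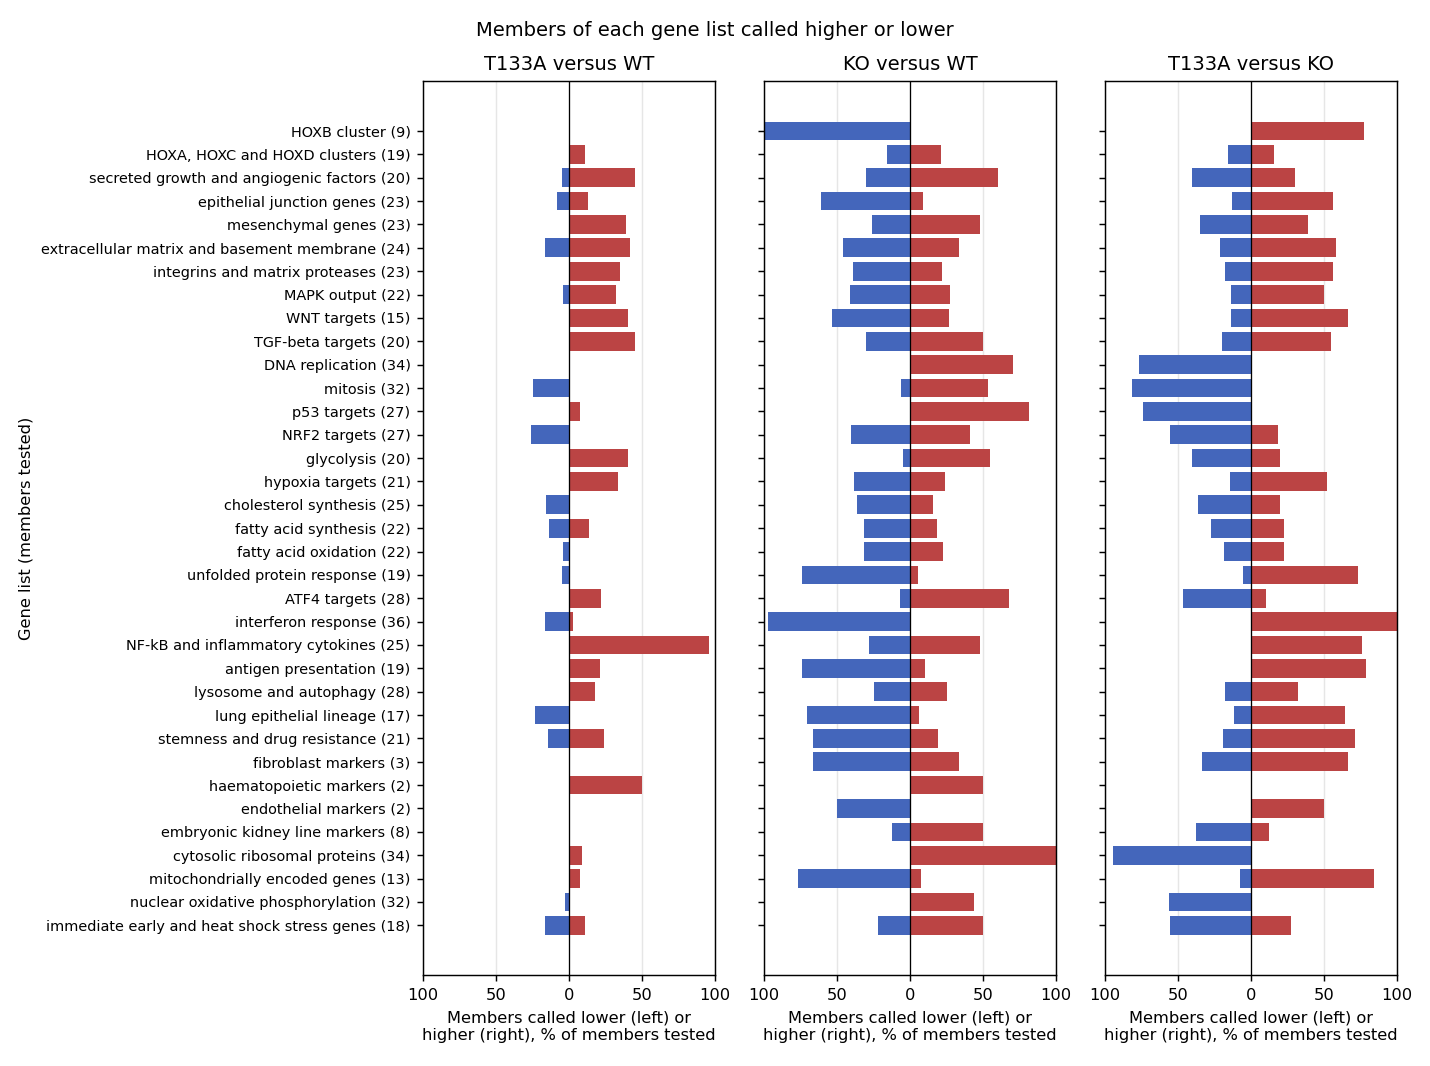
Share of each list's tested members called higher (right, red) or lower (left, blue) by edgeR in the 3 comparisons (horizontal axis, % of members tested; number tested in parentheses). NF-kB and cytokine genes are higher in 24 of 25 members in T133A against WT, and interferon response genes lower in 35 of 36 members in KO against WT.

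Across the lists, camera with its preset correlation called 18 of 33 tested in T133A against WT (14 up, 4 down), 15 in KO against WT (7 up, 8 down) and 21 in T133A against KO (14 up, 7 down). None held with an estimated correlation, where the lowest adjusted p was 0.100, 0.0624 and 0.0570. The rotation test fry, which asks whether a list's genes move one way on balance, called 12, 22 and 24 lists, of which 12, 14 and 20 were also called by camera. In T133A against WT fry did not call NRF2 targets (adjusted p = 0.071), cholesterol synthesis (0.162) or glycolysis (0.154). Nor did it call antigen presentation (0.106), ribosomal proteins (0.204) or mitochondrially encoded genes (0.238). It also missed glycolysis in KO against WT (0.0603) and NRF2 targets in T133A against KO (0.0559).

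Calls of the 2 comparisons against WT overlapped. Genes higher in both T133A and KO numbered 442 (216 if the lists were independent), genes lower in both 469 (149), genes higher in T133A and lower in KO 207 (210), and genes lower in T133A and higher in KO 29 (153). Members of the NF-kB and cytokine list were on both sides, with 11 higher in both and 7 higher in T133A and lower in KO, such as CXCL5 (775 ± 23.8 CPM in WT, 5290.5 ± 483 in T133A and 140.1 ± 6.25 in KO) and PTGS2 (1393 ± 109 CPM in T133A). Across 16340 genes the fold changes correlated with Pearson's r = 0.34, and their covariance was 0.155. Unchanged groups simulated against the same WT libraries gave a mean correlation of 0.498 and a covariance of 0.0338 over 100 simulations, and at most 1 shared call in 20 of them. The covariance thus exceeded the simulated value by 0.121. The WT libraries were too few to give each comparison 2 of its own, so part of the excess in shared calls may come from the shared controls. In a check chosen after the data were seen, T133A was compared with 1 WT library and KO with the other. No WT library was then shared, but anything common to the WT group still entered both comparisons. With WT replicate 1 for T133A the numbers were 191, 247, 98 and 18 (70.9, 59.4, 74.9 and 56.2 if the lists were independent) and the covariance 0.129. With WT replicate 2 for T133A they were 183, 217, 108 and 15 (74.3, 50.9, 76.1 and 49.7) and the covariance 0.119. Without WT replicate 1 the numbers were 191, 224, 98 and 12, without WT replicate 2 they were 204, 278, 92 and 11, and without T133A replicate 2 they were 850, 732, 268 and 45, and the last was 87 without T133A replicate 1.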

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

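The GC and length correction, the crossed block, separate WT libraries for T133A and KO, and leaving out mitochondrial genes were chosen only after the results were seen; the other settings were fixed before. No setting reversed a named gene that was called in either fit. Of 425 values of genes picked by the naming rule, however, 32 lost their call without WT replicate 1, 22 without WT replicate 2, 12 without T133A replicate 1, 6 without T133A replicate 2 and 3 without KO replicate 2. The number lost was 6 with DESeq2 and with library size only, 5 with the GC and length correction, 4 with the replicate block, and 1 with RLE size factors and with no low-count filter. The 3 counts of called genes stayed within 1.5 times the reported value with RLE size factors, library size only, DESeq2, limma-voom, no low-count filter, a minimum of 5 CPM, the 2 compared groups alone, or mitochondrial genes left out. DESeq2 called 1287 genes for T133A against WT, 6548 for KO against WT and 5620 for T133A against KO, and gave no adjusted p for 634 genes in the first.

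Leaving out each library moved the calls of T133A against WT from 763 (without WT replicate 1) to 2579 (without T133A replicate 2), those higher from 456 to 1447 and those lower from 307 to 1132; without WT replicate 2 they were 840, 467 and 373. The calls of KO against WT ran from 5306 to 8496, those higher from 2563 to 4418, and those of T133A against KO from 5112 to 6580. Each of these fits left 1 library in a group, which alone can lower the number called, and the cause was not tested. HOXB9 in T133A against WT ran from -0.047 (without T133A replicate 1) to 0.33 (without T133A replicate 2, adjusted p = 0.0202), since its 2 T133A libraries differed. Numbers shared between the comparisons with WT ran from 191 to 850 (both higher), 224 to 732 (both lower), 92 to 268 (higher in T133A, lower in KO) and 11 to 87 (lower in T133A, higher in KO); the last was 45 with library size only. List calls numbered 18 in T133A against WT and 15 in KO against WT whichever library was left out, and 19 to 23 in T133A against KO, though not always for the same lists.

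The GC and length correction gave 2622 genes for T133A against WT (1442 higher, 1180 lower; 1528 shared with the 1560), 8083 for KO against WT (6162 shared with the 7622) and 7463 for T133A against KO (5728 shared with the 6523). It gave 696, 752, 344 and 89 shared genes in the order above. Separate WT libraries gave 191, 247, 98 and 18 with WT replicate 1 for T133A and 183, 217, 108 and 15 with WT replicate 2 for T133A, as each comparison then had 1 WT library. A minimum log2 fold change of 1, which by construction keeps fewer genes, left 431 (285 higher, 146 lower), 2490 (757 and 1733) and 2097 (1509 and 588). With an estimated correlation camera called 0 lists in T133A against WT, 0 in KO against WT and 0 in T133A against KO. The preset value called 18, 15 and 21. A simulated list with planted changes had unadjusted camera p = 0.00067, 0.000855 and 0.000659 with an estimated correlation. It did not pass when adjusted with 100 unchanged lists (adjusted p = 0.0677, 0.0863 and 0.0665). Only 33 lists were adjusted together in the real data, and the simulated genes varied independently. Whether low power accounts for the 0 calls was therefore not settled. The NF-kB list in KO against WT was the only list to reverse, from up without a call to a fall with fry (adjusted p = 0.00422). Its members moved in both directions and fry tests another question, but the cause of the reversal was not tested.

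With the replicate number as a block, edgeR called 1419, 7165 and 6031 genes and camera 18, 15 and 21 lists, and no list call changed. Same-numbered libraries did not deviate together (correlations -0.05 for WT with T133A, 0.02 for WT with KO, -0.12 for T133A with KO). These values gave no sign of pairing but do not exclude it. Differences between replicates followed GC content (Spearman's rho -0.27 in WT, 0.69 in T133A and -0.42 in KO), which could hide a shared batch. The crossed pairing of T133A with KO called 7074. Depth limits genes of few counts, since a gene needs about 0.161 to 0.182 CPM to be told from 0 in a library.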

Other observations

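The families, transcription factors and single transcripts below were picked after their values were seen, and the tests on other cell types, copy loss and the kidney line were chosen only after the result was seen; those on GC content and on a trace line were written before.

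Members of several gene families were lower in KO than in WT. All 5 CEACAM genes tested, all 8 mucins and all 3 fibrinogen chains fell, as did all 8 CXC chemokines, under each of the 4 scalings tried. Of 11 claudins, 6 fell (7 with the GC and length correction), and of 11 UDP-glucuronosyltransferases, 9 fell and 1 rose (8 fell with library size only). T133A moved apart from KO in some of these families: 3 CEACAM genes, 6 CXC chemokines (7 with RLE size factors and with the GC and length correction) and 6 of 9 SERPINB serpins (5 with library size only, 7 with the correction) were higher than in WT, where KO had 6 serpins lower (and 1 higher with the correction). The mucins went the same way in both, with 5 lower in T133A, and no fibrinogen chain was called there. LCN2, an iron-binding protein of innate defence, stood at 30.7 CPM in WT, 342 CPM in T133A and 5.62 CPM in KO. CXCL1 stood at 49.4, 639 and 8.44 CPM.

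Among 1120 transcription factor genes tested, 243 were higher and 249 lower in KO, and 54 higher and 48 lower in T133A. Among all 16340 genes the numbers were 3862 and 3760 in KO and 912 and 648 in T133A, so factors were called at about the general rate. With a change of at least 1 on the log2 scale and at least 5 CPM in the higher group, the numbers of factors were 42 and 68 in KO and 13 and 3 in T133A. Of the factors picked out, those that fell in KO were CREB3L1 (log2 fold change -4.55), SPDEF (-3.52), EHF (-3.28), MECOM (-2.93) and HNF4A (-2.37). Those that rose were ALX4 (3.37), GLI3 (2.41), RUNX2 (2.15) and HMGA2 (1.49). All 3 NR4A nuclear receptors tested fell in KO. The difference between the 2 comparisons was tested only as T133A against KO.

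The rise of NF-kB and cytokine genes in T133A could come from other cells in those libraries or from their GC and length trends. Against a large share of fibroblast, haematopoietic or endothelial cells, 36 of their markers together went from 69.7 to 78.7 CPM. That was a gain of 0.111% of the gain of the NF-kB list (2147 to 10260 CPM). The gain expected from such cells was not known, so small numbers of them are not excluded. The most abundant of these markers, EGFL7 and LUM, stood at 33.1 and 21.3 CPM in WT. The markers do not cover epithelial cells, so cells of another epithelial line are not excluded by them. Against GC and length trends, all 24 members called higher were also called with the GC and length correction. A signal that differs between these cultures, the construct or the site of integration stays open, since the labels do not say whether a group was a single transduced population, and no vector control was measured.

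The fall of the whole HOXB cluster in KO could come from lost gene copies on chromosome 17. Against a loss over the wider region, the 22 flanking genes at 5 CPM or more had a median log2 fold change of 0.144. GC and length trends are argued against by 9 of 9 cluster genes still called lower with the correction. A narrower loss of some copies from SKAP1 to TTLL6, both also lower, stays open, as does a change in regulation; HOXB7 and HOXB13 within it fell by 0.48 and 0.58 on the log2 scale.

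Some transcripts were counted in the T133A libraries alone. With at least 10 counts in each library of a group and at most 2 over all others, there were 8 such genes for T133A, 2 for KO (DPF3 and AC019068.1) and 0 for WT. CSF3, SAA2, LTB, TNF and MIR3142HG are known NF-kB targets or acute-phase genes, but IRS4 (25 and 49 counts in T133A, 1 over the others), its neighbour AL035425.3 on chromosome X and the pseudogene AL356234.1 on chromosome 6 (13 and 21 counts, 1 over the others) are not known as such. CDKN2A, which A549 cells are known to lack, had 8 and 7 counts in T133A and 0 elsewhere. A trace of another line could bring these, but MTAP, also known to be lost in A549, decides nothing. It had 19 counts over T133A and 27 over the other 4 libraries. Of 11 embryonic kidney line markers listed beforehand, only 2 (EYA1 and PHOX2A) had a baseline low enough to show a trace from packaging cells. Both had 0 counts in T133A, and PHOX2A had 0 counts in every library. The count expected from such a trace was not known, so these zeros decide nothing. IRS4 was not on the kidney line list, so its counts in T133A did not enter this check. Neither source is excluded. Activation in the transduced cells stays open for the other genes, but not for CDKN2A if the cells lack it, and where its few counts came from was not settled.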
